A study of Mus musculus with 18 samples.

How the data were processed

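Messenger RNA from heart, kidney and liver of C57BL/6J mice on a ketogenic diet or chow was sequenced from stranded libraries, per the labels' protocols, which also state an RNA integrity number above 4. Per the submitters' processing notes, the tools used were bcl2fastq, HISAT2 2.1.0, SAMtools and featureCounts 1.5.0; versions of bcl2fastq and SAMtools are not given in the sources used here. Per the file headers, reads were counted with featureCounts on exons of the UCSC annotation of the mouse build mm9 and summed per gene, as read pairs with strandedness setting 2 and a minimum mapping quality of 2. Per the file headers the same options were used in all 18 files. Reads that map to several places and reads that overlap several genes were counted as fractions. The deposited values are therefore estimated counts that need not be whole. Genes with non-whole values held 46.2 to 72.1% of the count of a library, so a change in 1 member of a family of similar genes (Mup, Hist1, globin, Cyp2a, Cyp4a, Gstm and Acot genes) can be spread over the others, and such genes are reported as uncertain. The estimated counts were rounded to whole numbers before testing, which changed the total of a library by at most 0.00573%. Coordinates are those of the deposited files on mm9, from the first to the last exon; a reference of another build was not used here.

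Libraries were grouped by the organ and diet in the labels, with 3 replicates in each of 6 groups. For each organ, genes were kept by edgeR's filterByExpr, scaled by TMM and tested between the diets with edgeR 4.0.16 (quasi-likelihood test with robust dispersion, in R 4.3.3). All adjusted p-values of genes are from this test unless another tool is named, with Benjamini-Hochberg adjustment over the genes tested in that organ, and a gene passed at an adjusted p under 0.05. Log2 fold changes are ketogenic minus chow as edgeR's model gave them at its default prior count, so those of genes near 0 counts are little damped. A prior count of 3 was used for the log2 CPM values that camera tested, not for these fold changes. Levels are CPM, counts scaled to the effective library size within the organ. Differences between organs were tested as contrasts of log2 fold changes in 1 edgeR model of all 18 libraries and 6 groups, over 15495 genes. Overlaps between organs were compared with n1 × n2 / N and with two-sided Fisher's exact tests. Lists of genes of pathways and cell types were written before the data were examined, as were the tests, the rule for naming genes and all alternatives not said to be added later; 39, 40 and 38 lists had at least 5 tested genes in heart, kidney and liver. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and adjusted over the lists of an organ. At that threshold 11, 16 and 9 lists passed in heart, kidney and liver. With a correlation estimated per list none passed by camera (lowest adjusted p = 0.165, 0.392 and 0.113), and the self-contained test fry called 19, 6 and 20.

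The text names 18 genes fixed in advance, the 8 largest rises and 8 largest falls per organ among genes that passed, had an average log2 CPM of at least 2 and showed no overlap of the 3 ketogenic and 3 chow libraries (predicted genes left out). It also names up to 4 members per discussed list with the smallest adjusted p, the 5 genes per pair of organs with the smallest p of the difference, and up to 10 genes shared by the 3 organs. Members of lists named beyond this rule, and Myl4, Sln, Plin1, Adipoq, Xist and Ddx3y, were chosen after their values were seen. Some genes that the rule names are not reported here. A fold change against 1 to 3 counts is not given as a bound.

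On simulated counts with the real means, library sizes and spread, the heart step recovered 67.2, 92.5 and 98.5% of genes changed 1.5-, 2- and 4-fold over 13304 genes, the kidney step 55.2, 89.6 and 97.0% over 14412 genes, and the liver step 77.6, 98.5 and 100% over 12830 genes. False calls were 9.47, 7.47 and 6.12% of all calls. The step for a difference between heart and kidney recovered 86% and 98% of genes that differed 2- and 4-fold, over 15377 genes. The changed genes were drawn from those with a mean of at least 4 CPM, so recovery at lower levels was not measured. All libraries were simulated as independent, with a spread estimated with ketogenic replicates 1 and 2 of heart and of liver as separate samples. The rates for heart and liver therefore do not hold if each of these pairs is 1 sample. The alternatives tried were DESeq2 1.42.0, limma-voom, RLE and total-count scaling, no filter and a stricter filter (CPM of 1 in 3 libraries), a test against 1.5-fold, an adjusted p under 0.1, all 18 libraries in 1 model, the replicate number as a block, a prior count of 1, and leaving out each library in turn. Summing ketogenic replicates 1 and 2 of heart and of liver, and leaving out chow heart replicate 3 together with ketogenic kidney replicate 1, were added after the data were seen, as were the regroupings with these sums and the test of lists between organs. Where nothing else is known of the animals, p-values measure the spread between these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.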

Results

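RNA sequencing was carried out on heart, kidney and liver of wild-type C57BL/6J mice, an inbred laboratory strain. From 4 weeks of age the mice ate either a ketogenic diet, with 90% fat, 9.7% protein and 0.3% carbohydrate, or standard chow, for 21 days. Each organ and diet was represented by 3 libraries that the labels call biological replicates, which gave 18 libraries in 6 groups. Every library listed estimated counts for the same 22609 gene symbols. The total count of a library ran from 16135276 to 22767878 in heart, from 16173996 to 19923905 in kidney and from 18151967 to 23835383 in liver. The title of the series names p53-dependent senescence in several organs. The question put to each organ is thus which genes differed between the diets, and which genes of the p53 and senescence programs were among them. The figures after "±" are SDs between libraries, and they cover sampling and animal-to-animal spread together.

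Libraries within a group were compared first. In heart and in liver, ketogenic replicates 1 and 2 differed by little more than counting noise. A chi-square test of their counts gave a median over genes of 0.664 in heart and 0.671 in liver, where counting alone gives 0.455. The other 16 pairs of libraries within a group gave 1.22 to 4.07. Their coefficient of variation beyond counting was 2.16% in heart and 2.54% in liver, against 5.31 to 11.2% in the other pairs. Each of these pairs was therefore counted as 1 sample in every mean and SD, so that n = 2 for the ketogenic heart and liver. The adjusted p-values in heart and liver come from all 6 libraries and are too small if each pair came from 1 mouse. The libraries also differed in tissue. Chow heart replicate 3 held 47522 counts of the atrial myosin light chain Myl7, 51505 of Myl4 and 12445 of the atrial calcium pump regulator Sln, where the other heart libraries held at most 266, 349 and 63. That library also held 1007 counts of the fat-droplet gene Plin1 and 589 of Adipoq, against at most 12 and 6 in the other hearts. Among the kidneys, only leaving out ketogenic replicate 1 raised the number of genes that passed, from 1314 to 3402.

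**Figure D1:**
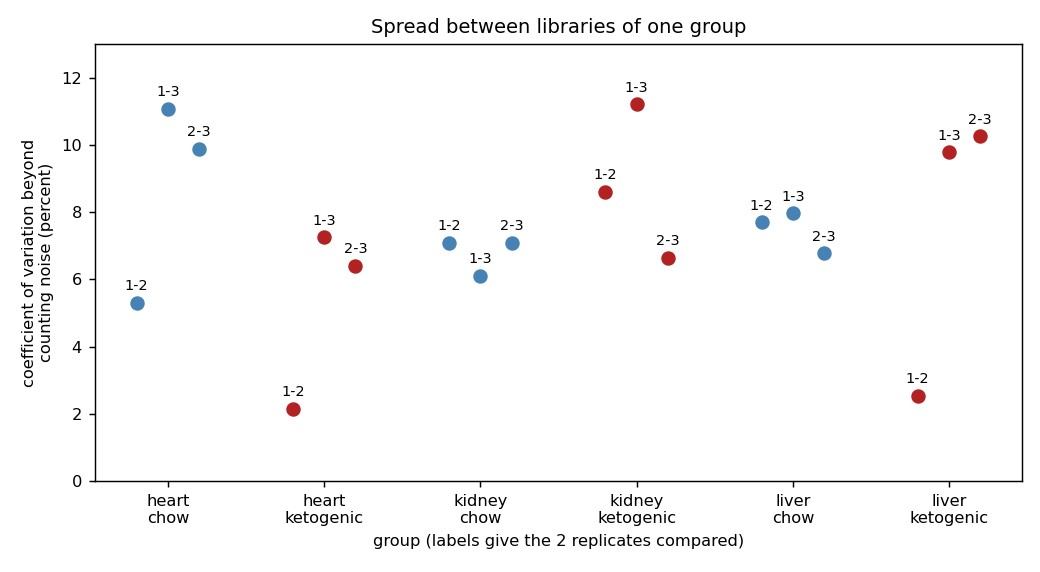
Coefficient of variation between replicates beyond counting noise (percent, axis from 0) for each of the 18 pairs of libraries within a group, 1 point a pair. Ketogenic replicates 1 and 2 of heart and of liver lie at 2.16% and 2.54%, and the other 16 pairs at 5.31% to 11.2%.

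In the heart, the ketogenic diet went with higher levels of genes that burn fat. Pdk4, a kinase that holds back glucose oxidation (chromosome 6, 5433351 to 5446278, minus strand, mm9), rose from 335 ± 22.2 CPM on chow (n = 3) to 2548 ± 243 CPM on the ketogenic diet (n = 2). Its log2 fold change was 2.96 (SE 0.10, adjusted p = 5.37e-06 by edgeR's quasi-likelihood test). Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 0.95 on the log2 scale (adjusted p = 0.000682), and Angptl4, an inhibitor of lipoprotein lipase, by 1.63 (adjusted p = 0.00173). Of 22 mitochondrial beta-oxidation genes, 18 rose and 4 did not pass the test (19 rose adjusted over the list alone). They included Ech1, which rose by 1.66, Decr1 by 1.63, Hadha by 1.45 and Acaa2 by 1.10 on the log2 scale. The list as a whole moved up (camera with a preset correlation, adjusted p = 3.90e-12; adjusted p = 0.442 with an estimated correlation). Of 31 genes that the fatty acid receptor PPAR-alpha drives, 26 rose, also when adjusted over the list alone (adjusted p = 6.18e-17; adjusted p = 0.165 with an estimated correlation). Of 22 peroxisomal genes 13 rose (14 adjusted over the list alone), such as Pex11a by 1.80, Crat by 1.18 and Cat by 1.15 (adjusted p = 1.06e-06; adjusted p = 0.165 with an estimated correlation). Of 20 genes of the tricarboxylic acid cycle 8 rose (9 adjusted over the list alone), such as Idh2 by 0.66 and Suclg2 by 0.58 (adjusted p = 0.000339; adjusted p = 0.600 with an estimated correlation; 0.0669 by fry). The 10 genes of ketone body metabolism did not move together by camera. In this list 2 rose and 2 fell (2 and 3 adjusted over the list alone), with Acat1 at 0.80 and Bdh2 at -3.37. Its median was -0.22 (adjusted p = 0.848). Fry, which tests whether the genes of a list move one way on balance, put the list upward, against the sign of its median (adjusted p = 0.00587). Oxct1 and Bdh1, which peripheral tissues use to oxidise ketone bodies, had log2 fold changes of -0.48 (adjusted p = 0.056) and -0.32 (adjusted p = 0.556). Both passed without chow replicate 3, at -0.63 (adjusted p = 0.000176) and -0.61 (adjusted p = 0.00589). DESeq2 called Oxct1 with all libraries (adjusted p = 0.0101).

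Clock genes and the genes with the largest changes in heart included several outside fuel use. Arntl and Npas2, activators of the circadian clock, fell by 2.22 and 1.37 on the log2 scale, while the clock-controlled genes Gm129, Per2, Bhlhe41 and Tef rose by 3.65, 2.39, 1.44 and 1.10. Of the 18 clock genes 12 rose and 3, Nfil3 being the third, fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.00251; adjusted p = 0.432 with an estimated correlation). Among the 8 largest rises were Scn4b, a sodium channel subunit (4.30, adjusted p = 0.000835), Chrna2, a nicotinic receptor subunit (4.18, adjusted p = 6.79e-05), and Acsm5, an acyl-CoA synthetase (2.60, adjusted p = 0.000382). Acot1, also among them at 2.70, shares reads with near-identical thioesterase genes and is uncertain. Genes of dividing cells and of the matrix fell. Of 39 proliferation genes 30 fell and 9 did not pass (33 fell and 1 rose adjusted over the list alone). Nusap1, Hmmr and Bub1b were at -2.54, -2.53 and -1.92, and the list passed (adjusted p = 4.77e-11; adjusted p = 0.474 with an estimated correlation). Of 34 matrix genes 27 fell and 1 rose (29 and 1 adjusted over the list alone). Col1a1 was at -1.62, Sparc at -1.44 and Col5a1 at -1.25, and the list passed (adjusted p = 3.90e-12; adjusted p = 0.165 with an estimated correlation). Marker genes of other cells moved too. Of 11 macrophage markers 10 fell, also when adjusted over the list alone, such as Lyz2 by 0.97, C1qb by 0.72 and Csf1r by 0.62 (adjusted p = 4.74e-06; adjusted p = 0.432 with an estimated correlation). Of 8 erythroid markers 6 fell (8 adjusted over the list alone), with a median of -2.08 (adjusted p = 0.000308; adjusted p = 0.474 with an estimated correlation). Of 11 fibroblast markers 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0129; adjusted p = 0.474 with an estimated correlation). The mean log2 CPM of the erythroid markers was 3.74, 4.15 and 5.35 in the ketogenic hearts and 6.28, 6.61 and 6.72 in the chow hearts. Of the 19 insulin and FOXO target genes 8 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0436; adjusted p = 0.442 with an estimated correlation). The list's call was lost without ketogenic replicate 3 (0.102), chow replicate 1 (0.0918) or chow replicate 3 (0.0644). In all, 3317 of 13411 heart genes passed, 1676 higher and 1641 lower on the ketogenic diet. Leaving out ketogenic replicate 1 or 2 left 1604 and 1583 genes, and summing that pair into 1 library left 1642, of which 1638 were among the 3317. Of 150 named genes called in heart, 37 lost the call when some 1 library was left out, against 67 of 116 in kidney and 11 of 161 in liver. With the near-identical pair as 1 library, 36 of the 150 in heart and 7 of the 161 in liver lost the call. Scaled by total count alone, the median of all genes lay at -0.16 and 23.4% of the called genes were higher, against 50.5%.

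In the kidney, the ketogenic diet went with lower levels of cell cycle and matrix genes, and single genes of several kinds rose. Azgp1, a secreted glycoprotein linked to fat breakdown, rose by 4.34 on the log2 scale (adjusted p = 0.000555) and Cyp7b1, an oxysterol hydroxylase, by 3.05 (adjusted p = 0.00298). Cyp2a4, a steroid hydroxylase (chromosome 7, 27092211 to 27100107, plus strand, mm9), went from 10.8 ± 4.32 to 343.9 ± 50.8 CPM (n = 3 each), a rise of 31.9-fold (adjusted p = 0.000881). It shares reads with its near-identical neighbour Cyp2a5 (log2 fold change 3.20), so the split between them is uncertain. Of 39 proliferation genes 33 fell and 6 did not pass (38 fell adjusted over the list alone). Bub1, Cenpf and Ccna2 were at -3.05, -2.93 and -2.85, and the list passed (camera adjusted p = 3.57e-25; adjusted p = 0.625 with an estimated correlation). Of 33 matrix genes 19 fell and 1, Ctgf, rose by 0.45 (24 and 1 adjusted over the list alone). Col1a2 was at -1.67, Sparc at -1.52 and Col4a1 at -1.29, and the list passed (adjusted p = 2.07e-14; adjusted p = 0.636 with an estimated correlation). The call of Ctgf was lost without ketogenic replicate 3 or any 1 of the chow replicates, up to an adjusted p of 0.105. Of 11 fibroblast markers 5 fell, also when adjusted over the list alone (adjusted p = 0.00517; adjusted p = 0.636 with an estimated correlation; 0.0822 by fry). Of 18 clock genes 12 rose and 3 fell, also when adjusted over the list alone. Arntl was at -1.68, Npas2 at -1.52 and Tef at 0.88, and the list passed (adjusted p = 0.000399; adjusted p = 0.392 with an estimated correlation).

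Lists of fatty acid genes passed upward in the kidney by camera at the preset correlation, while most of their members did not pass and fry called none of these lists (adjusted p = 0.0822 for beta-oxidation and PPAR-alpha targets and 0.142 for peroxisomal genes). Without ketogenic replicate 1, 46 genes of the beta-oxidation, PPAR-alpha and ketone lists together passed, against 21 with all libraries. Of 22 beta-oxidation genes 8 rose (12 adjusted over the list alone), Acads by 0.70 among them (adjusted p = 2.12e-05; adjusted p = 0.636 with an estimated correlation). Of 39 PPAR-alpha targets 12 rose (24 adjusted over the list alone; adjusted p = 2.34e-08; adjusted p = 0.636 with an estimated correlation). Of 24 peroxisomal genes 8 rose and 1 fell (12 and 2 adjusted over the list alone; adjusted p = 3.52e-05; adjusted p = 0.643 with an estimated correlation). Angptl4 rose by 1.04 (adjusted p = 0.00744), but not without chow replicate 1 (adjusted p = 0.0524). Cpt1a rose by 0.60 (adjusted p = 0.024), and its call was lost without ketogenic replicate 2 (0.0878) or 3 (0.0777) or chow replicate 1 (0.123), 2 (0.0571) or 3 (0.094). Pdk4 was at 0.22 (adjusted p = 0.628) with all libraries and passed without ketogenic replicate 1, at 0.46 (adjusted p = 0.0219). Bdh1 fell by 0.71 (adjusted p = 0.00212). Oxct1 was at -0.29 (adjusted p = 0.136), and passed without ketogenic replicate 1 (-0.36, adjusted p = 0.0177) and by DESeq2 (adjusted p = 0.0218). Of 25 antioxidant genes 6 rose (8 adjusted over the list alone; adjusted p = 0.0028; adjusted p = 0.392 with an estimated correlation). The 11 adipocyte markers had a median of 1.86 (adjusted p = 0.00749; adjusted p = 0.643 with an estimated correlation; 0.309 by fry; 0.0516 without chow replicate 1). Adipoq was counted 556, 50 and 716 times in the ketogenic kidneys against 12, 145 and 170 times in the chow kidneys. In all, 1314 of 14526 kidney genes passed, 522 higher and 792 lower. This count moved with every library. It was 3402 without ketogenic replicate 1, 565 without 2 and 672 without 3, and 412, 789 and 599 without chow replicates 1, 2 and 3. Scaled by total count alone, 25.3% of the called genes were higher, against 39.7%.

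**Figure D2:**
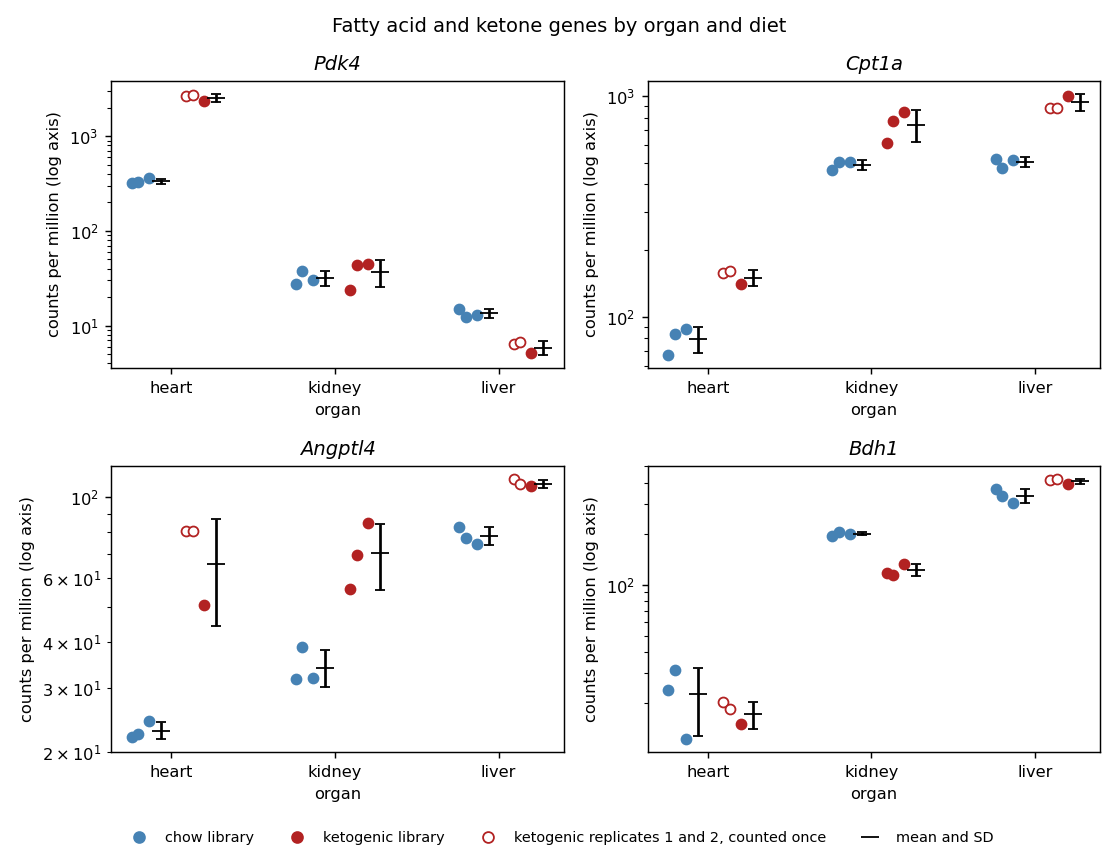
Level of Pdk4, Cpt1a, Angptl4 and Bdh1 (CPM, log axis) in each library of heart, kidney and liver on chow and on the ketogenic diet, with the mean and SD of each group as a bar; open circles mark the near-identical pair that was counted once. Mean Pdk4 is 2548, 37.2 and 5.86 CPM on the ketogenic diet against 335, 31.9 and 13.5 CPM on chow in heart, kidney and liver.

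In the liver, genes of fat synthesis fell and genes of fat oxidation, cholesterol synthesis and respiration rose. Scd1, which makes monounsaturated fatty acids (chromosome 19, 44468940 to 44482199, minus strand, mm9), dropped from 10190 ± 1428 CPM on chow (n = 3) to 134.5 ± 21.2 CPM (n = 2). Its log2 fold change was -6.30 (adjusted p = 2.24e-09). Of 25 genes of fatty acid and triglyceride synthesis 15 fell and 3 rose (15 and 4 adjusted over the list alone). Pnpla3 was at -5.10, Acacb at -2.32 and Pklr at -1.43, and the list passed (camera adjusted p = 0.002; adjusted p = 0.315 with an estimated correlation). Of 22 beta-oxidation genes 19 rose, also when adjusted over the list alone, such as Hsd17b10 by 1.40 and Acadm by 1.12 (adjusted p = 4.45e-08; adjusted p = 0.480 with an estimated correlation). Of 38 PPAR-alpha targets 28 rose and 3 fell, also when adjusted over the list alone (adjusted p = 1.71e-08; adjusted p = 0.464 with an estimated correlation). Those that rose included Cidec, a lipid droplet protein, from 0.592 ± 0.150 to 28.9 ± 0.724 CPM (5.59, adjusted p = 7.50e-09), and the fatty acid carriers Cd36 (2.00) and Slc22a5 (1.57). Pdk4 fell by 1.15 (adjusted p = 4.53e-05). Of 24 peroxisomal genes 15 rose and 4 fell (15 and 5 adjusted over the list alone; adjusted p = 0.0113; adjusted p = 0.631 with an estimated correlation). Cpt1a and Angptl4 rose by 0.87 (adjusted p = 1.44e-05) and 0.48 (adjusted p = 0.000359). Of the 10 genes of ketone body metabolism 5 rose and 1, the transporter Slc16a1, fell (adjusted p = 0.123 by camera and, upward, 0.0242 by fry), with Acat1 at 1.11. Bdh1 was among them at 0.30 (adjusted p = 0.0154). Its call was lost without ketogenic replicate 1 (0.0591) or 2 (0.0689), without chow replicate 2 (0.0532) or 3 (0.0606), with the near-identical pair as 1 library (0.0609) and with all 18 libraries in 1 model (0.331). Oxct1 had a log2 fold change of 0.16 (adjusted p = 0.496).

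Of 25 genes of cholesterol synthesis in liver 17 rose and 1 fell, also when adjusted over the list alone, such as Sc4mol by 1.65 and Idi1 by 1.36 (camera adjusted p = 0.000287; adjusted p = 0.464 with an estimated correlation). Of 38 genes of oxidative phosphorylation 21 rose and 1 fell, also when adjusted over the list alone, such as Ndufb9 by 1.29 and Cox7b by 1.24 (adjusted p = 0.000193; adjusted p = 0.653 with an estimated correlation). Of 39 proliferation genes 35 fell and 4 did not pass, also when adjusted over the list alone. Ccnb1, Plk1 and Tpx2 were at -4.79, -4.45 and -4.15, and the list passed (adjusted p = 1.52e-15; adjusted p = 0.464 with an estimated correlation). Of 33 matrix genes 25 fell and 2 rose, Dcn (0.39) among them, also when adjusted over the list alone. Col1a2 was at -1.67 and Col3a1 at -1.64, and the list passed (adjusted p = 1.94e-07; adjusted p = 0.113 with an estimated correlation). Of 31 interferon response genes 16 rose and 2 fell (18 and 3 adjusted over the list alone). Psmb9 was at 1.36, Ifi44 at 1.24 and Bst2 at -0.58, and the list passed (adjusted p = 0.0283; adjusted p = 0.822 with an estimated correlation). That call was lost without ketogenic replicate 2 (0.0546) or chow replicate 3 (0.108) and with the near-identical pair as 1 library (0.0502), and fry gave 0.0818. Clock genes went both ways, with 8 of 18 up and 5 down, also when adjusted over the list alone (adjusted p = 0.274 by camera and, upward, 0.0289 by fry). Npas2 and Arntl were at -4.36 and -3.93, and Bhlhe41 and Per2 at 5.29 and 2.30. The largest rise was Cfd, an adipocyte serine protease (chromosome 10, 79353598 to 79355401, plus strand), which had 2256, 2210 and 1044 counts on the ketogenic diet against 1, 2 and 1 on chow (adjusted p = 0.000119). Among the largest falls were Hao2, a peroxisomal oxidase (-6.45, adjusted p = 0.00142), Cdc20, a regulator of mitosis (-6.23, adjusted p = 8.13e-07), and Igf2bp3, an RNA-binding protein of fetal tissue (-5.84, adjusted p = 1.83e-06). In all, 6164 of 12947 liver genes passed, 3146 higher and 3018 lower. With ketogenic replicates 1 and 2 summed into 1 library 4869 passed, of which 4826 were among the 6164.

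**Figure D3:**
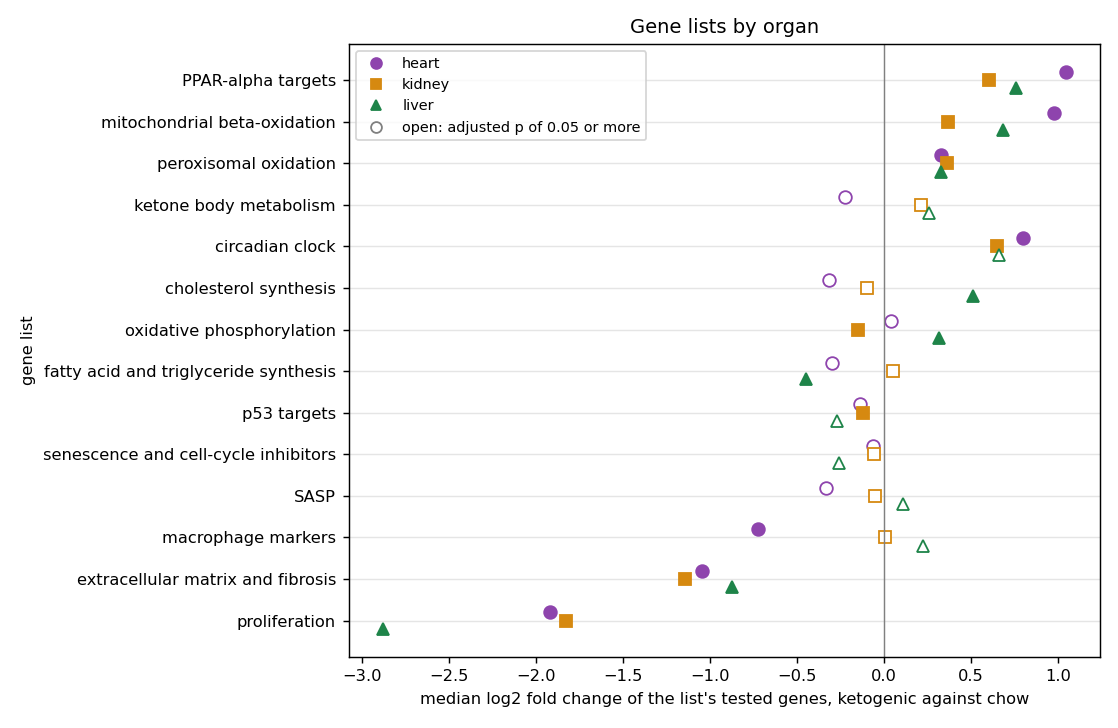
Median log2 fold change, ketogenic against chow, of the measured genes of 14 fixed lists in heart, kidney and liver; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation and open symbols the others. The proliferation list lies at -1.92, -1.83 and -2.88 and the matrix list at -1.05, -1.14 and -0.87 in heart, kidney and liver.

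Genes of the p53 and senescence programs were lower or moved both ways on the ketogenic diet. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21 (chromosome 17, 29227931 to 29237667, plus strand, mm9), fell in heart from 31.4 ± 5.15 (n = 3) to 13.4 ± 4.64 CPM (n = 2). Its log2 fold change was -1.36 (SE 0.23, adjusted p = 0.00685). In kidney it fell from 9.10 ± 1.49 to 4.18 ± 1.23 CPM (n = 3 each; -1.11, SE 0.23, adjusted p = 0.0188) and in liver from 9.38 ± 2.93 (n = 3) to 1.45 ± 0.754 CPM (n = 2; -2.52, SE 0.35, adjusted p = 0.000628). The kidney call was lost without ketogenic replicate 2 (0.0692), chow replicate 1 (0.0885) or chow replicate 2 (0.0659). Tested against a 1.5-fold change instead of none, Cdkn1a passed in liver and not in heart (adjusted p = 0.0766) or kidney (0.225). Trp53, which encodes p53 (chromosome 11, 69393861 to 69405375, plus strand), fell in heart from 25.2 ± 2.75 to 15.9 ± 4.91 CPM (-0.78, SE 0.19, adjusted p = 0.0244) and in liver from 27.2 ± 2.96 to 15.6 ± 6.21 CPM (-0.95, SE 0.24, adjusted p = 0.0181), and was at -0.25 in kidney (adjusted p = 0.418). Its heart call was lost without ketogenic replicate 1 (0.103) or 2 (0.0617), without chow replicate 1 (0.0691) or 2 (0.0765) and with the near-identical pair as 1 library (0.077). The liver call was lost without ketogenic replicate 2 (0.0747) or chow replicate 2 (0.0508) or 3 (0.0606). Mdm2, the ubiquitin ligase of p53 (chromosome 10, 117125961 to 117147772, minus strand), rose in liver (0.41, adjusted p = 0.00501) and was at 0.06 in heart (adjusted p = 0.559) and in kidney (adjusted p = 0.636). Ccng1, another p53 target, rose in liver (0.57, adjusted p = 0.000599), was at 0.05 in heart (adjusted p = 0.808) and fell in kidney (-0.39, adjusted p = 0.0302). The kidney call was lost without ketogenic replicate 2 (0.116) or chow replicate 1 (0.13), 2 (0.0746) or 3 (0.0516) and with all 18 libraries in 1 model (0.0588). Casp2, a protease that cleaves Mdm2, fell in liver (-0.61, adjusted p = 0.00561), and was at -0.17 in kidney (adjusted p = 0.262). In heart it was at -0.28 (adjusted p = 0.0777) and passed without chow replicate 3 (0.03). Lmnb1, a nuclear lamina gene that is lost in senescent cells (chromosome 18, 56867467 to 56913079, plus strand), fell by 1.52 in heart (adjusted p = 0.00462), 1.19 in kidney (adjusted p = 0.00255) and 1.25 in liver (adjusted p = 2.82e-05). A fall of Lmnb1 goes with senescence and a fall of Cdkn1a against it, so these genes do not point the same way. Proliferation genes fell in the same organs, and whether the fall of Lmnb1 is part of that was not tested.

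**Figure D4:**
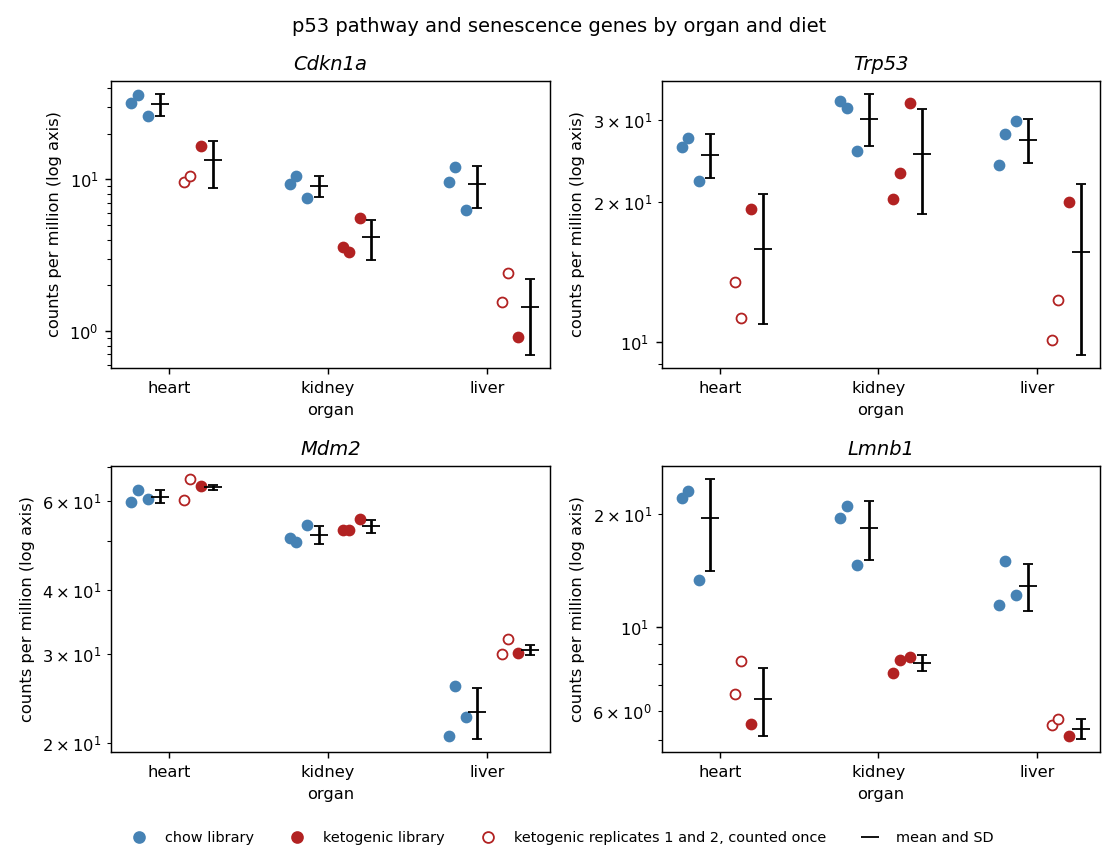
Level of Cdkn1a, Trp53, Mdm2 and Lmnb1 (CPM, log axis) in each library of heart, kidney and liver on chow and on the ketogenic diet, with the mean and SD of each group as a bar; open circles mark the near-identical pair that was counted once. Mean Cdkn1a is 13.4, 4.18 and 1.45 CPM on the ketogenic diet against 31.4, 9.10 and 9.38 CPM on chow.

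As a list, the p53 targets fell in kidney and passed in neither of the other organs. In kidney 8 of 32 fell and 24 did not pass (11 fell and 1 rose adjusted over the list alone), with Plk2 at -0.59 (adjusted p = 0.00741). The list's adjusted p was 0.0194 by camera, with a median of -0.12, and adjusted p = 0.643 with an estimated correlation. It was 0.0896 without ketogenic replicate 1, 0.0512 without chow replicate 1 and 0.0822 by fry. In heart 3 of 31 rose and 8 fell (4 and 8 adjusted over the list alone), such as Gadd45a, a DNA damage gene (0.63), and Phlda3, a p53-induced repressor of Akt (-1.23). The heart list had an adjusted p of 0.188 by camera and, downward, 0.0229 by fry. In liver 6 of 30 rose and 9 fell (7 and 9 adjusted over the list alone; adjusted p = 0.402), such as Perp (0.51), Gtse1, a cell cycle gene (-2.87), and Bbc3, a killer protein of the Bcl-2 family (-1.69). Of all genes tested, 3317 of 13411 passed in heart, 1314 of 14526 in kidney and 6164 of 12947 in liver. Of the senescence and cell cycle inhibitor genes, 1 of 17 rose and 4 fell in heart (1 and 5 adjusted over the list alone; adjusted p = 0.345), the rise being Rbl2 (0.45). In kidney 2 of 18 rose and 4 fell (2 and 6; adjusted p = 0.381), Cdkn1c at -0.61 among them, and in liver 2 of 17 rose and 8 fell (3 and 8; adjusted p = 0.338 by camera and, downward, 0.00342 by fry), such as Bmi1, a repressor of the Cdkn2a locus (0.81), and Glb1, the lysosomal galactosidase (-0.81). Cdkn2a, the senescence marker gene of p16, was too low to test. Its counts summed to 4 on the ketogenic diet and 21 on chow in heart, to 1 and 3 in kidney and to 3 and 5 in liver. Of the genes that senescent cells secrete, 2 of 37 rose and 6 fell in heart, also when adjusted over the list alone (adjusted p = 0.12). In kidney 2 of 35 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.891), and 6 of 33 rose and 3 fell in liver, also when adjusted over the list alone (adjusted p = 0.443). In liver Il1b, an inflammatory cytokine, rose by 1.31 (adjusted p = 0.00952), and Igfbp3 fell by 1.42. In heart Igfbp7 fell by 1.16 (adjusted p = 4.79e-05). Il1b was at 1.03 in kidney (adjusted p = 0.121) and was not tested in heart, with 22 counts on the ketogenic diet and 21 on chow. Tnf was at -0.75 in heart (adjusted p = 0.357) and too low to test in kidney and liver, as was Il6 in each organ. The stress hormone Gdf15 was at 0.60 in heart (adjusted p = 0.166), -0.44 in kidney (adjusted p = 0.354) and -0.74 in liver (adjusted p = 0.12), where it passed at -1.01 without chow replicate 3 (adjusted p = 0.0171). Fgf21, a fasting hormone, was at 1.93 in liver by edgeR (adjusted p = 0.174), passed by limma-voom (0.0405) and with all 18 libraries in 1 model (0.048), and was too low to test in heart and kidney. Of 30 AMPK, sirtuin, caspase-2 and p53 regulator genes, 9 rose and 2 fell in heart (adjusted p = 0.12 by camera and, upward, 0.0171 by fry), 3 rose and 1 fell in kidney (adjusted p = 0.378), and 6 rose and 9 fell in liver (adjusted p = 0.807).

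Whether the diet acted alike in the organs was tested as the difference of log2 fold changes in 1 model of all 18 libraries. Heart and kidney differed for 842 of 15495 genes, of which 56 were called in opposite directions. Acsf2, an acyl-CoA synthetase, was at 1.91 in heart and -0.29 in kidney (difference 2.19, adjusted p = 3.05e-07), Scn4b at 4.30 and 0.03 (4.26, adjusted p = 4.45e-07), and Pdk4 at 2.96 and 0.22 (2.73, adjusted p = 1.53e-05). Impa2, an inositol phosphatase, was at 1.30 and -0.79 (2.07, adjusted p = 2.94e-06). Heart and liver differed for 5066 genes, 753 of them called in opposite directions. Pdk4 differed by 4.14 (adjusted p = 7.09e-08), Acacb, which makes the malonyl-CoA that restrains fat oxidation, by 3.38 (1.03 in heart and -2.32 in liver, adjusted p = 2.87e-08), and Angptl4 by 1.18 (adjusted p = 0.000818). Gstm1 differed by 2.97 (adjusted p = 1.61e-08) but shares reads with its paralogs. Kidney and liver differed for 4532 genes, 104 of them called in opposite directions. Apoa4, an apolipoprotein, was at -1.26 in kidney and 2.71 in liver (difference -3.93, adjusted p = 2.76e-08). Azgp1 differed by 3.88 (adjusted p = 1.35e-07), Ccng1 by -0.92 (adjusted p = 0.000794) and Pdk4 by 1.41 (adjusted p = 0.0011). The fall of Cdkn1a was larger in liver than in heart by 1.20 (adjusted p = 0.0472) and than in kidney by 1.45 (adjusted p = 0.027), while heart and kidney did not differ detectably (adjusted p = 0.803). The difference of heart and liver was lost without replicate number 1 (0.218) or 2 (0.0583), with the near-identical pairs as 1 library each (0.0541) and without chow heart replicate 3 and ketogenic kidney replicate 1 (0.107). It was also lost by limma-voom and with the 12 libraries of the 2 organs alone. The difference of kidney and liver was lost without replicate number 1 (0.196) and by limma-voom. Trp53 did not differ between heart and kidney (adjusted p = 0.405), heart and liver (0.72) or kidney and liver (0.112) in a way the test could detect, and Lmnb1 likewise gave 0.567, 0.569 and 0.861. Without replicate numbers 1, 2 and 3 the count for heart and kidney was 328, 37 and 460. Without numbers 1 and 2 it was 2641 and 2335 for heart and liver and 2398 and 1896 for kidney and liver. With the near-identical pairs as 1 library each, 392 genes differed between heart and kidney.

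The organs also shared changes. Of 11872 genes tested in all 3 organs, 240 were lower and 68 higher on the ketogenic diet in every organ, 308 in all, where independent lists of these sizes would share 18.1 and 12.7 genes. A further 46 were called in all 3 with mixed directions. The shared falls included the clock activators Arntl (chromosome 7, 120350979 to 120457640, plus strand, mm9; -2.22 in heart, -1.68 in kidney and -3.93 in liver) and Npas2 (-1.37, -1.52 and -4.36). Also shared were falls of the matrix protein Sparc (chromosome 11, 55208003 to 55233582, minus strand; -1.44, -1.52 and -1.26), the collagen Col15a1 (-1.17, -1.44 and -1.63), the membrane protease Mmp14 (-1.05, -0.88 and -0.89) and the secreted glycoprotein Fstl1 (-1.68, -1.29 and -0.91), and of Anln, which acts in cell division (-2.51, -2.32 and -2.33). These calls held when any 1 library was left out. The histone gene Hist1h2bn also fell in the 3 organs, but histone genes share reads. Of genes tested in both organs, heart and kidney shared 367 falls where independent lists would share 86.5 (odds ratio 9.85, Fisher's exact test p = 9.00e-158, two-sided) and 149 rises where they would share 53.5 (odds ratio 4.01, p = 5.12e-34). Kidney and liver shared 378 falls (odds ratio 4.72) and 180 rises (odds ratio 1.94). Heart and liver shared 493 falls (odds ratio 1.82) but 317 rises, fewer than the 362.5 of independent lists (odds ratio 0.822, Fisher's exact test p = 0.00336, two-sided). Genes are not independent, so these p-values describe the lists and not the mice. It is not known whether the same mice gave the 3 organs. If they did, another difference between the groups of mice, such as the hour of collection, would be shared by the organs too. Without replicate numbers 1, 2 and 3 in every group, 106, 5 and 175 genes were shared by the 3 organs, and 221 with the near-identical pairs as 1 library each, of which 217 were among the 308.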

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

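The regroupings with the near-identical libraries summed, and the test of the kidney library by its proliferation, matrix and clock genes, were chosen after the result was seen; the other tests in this part were chosen before the data were examined or before the tested values were seen.

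The effect of the diet differed between organs, by the test of the difference of log2 fold changes, for 842 genes between heart and kidney, 5066 between heart and liver and 4532 between kidney and liver. With the diets regrouped within both organs, 1 of 33 splits for each pair, the real one, reached these counts, and the highest of the others gave 339, 4880 and 3654 genes. These splits part the near-identical libraries, which are not exchangeable with others, so they decide nothing about chance. With each near-identical pair summed into 1 library, the real grouping gave 392, 3693 and 3417 genes and the highest other 636, 2132 and 2833. For heart and kidney 2 of 33 splits reached the real count, the real one and 1 with 636 genes that kept the real diets of the kidney. Since that split keeps the kidney's effect, it says little about chance, which this test cannot exclude. For each pair with liver only 1 of 33 splits reached the real count, the real one. Because the diets were shuffled in both organs, that share is measured against no diet effect in either organ. It cannot exclude chance for a difference between 2 diet effects. Some of the splits keep the real diets of 1 organ, which leaves its effect in the difference; the highest of the others gave 20, 3 and 17 genes.

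Between heart and kidney, the named differences (heart minus kidney, log2) were those of Acsf2 (2.19), Scn4b (4.26), Impa2 (2.07), Pdk4 (2.73), the matrix-binding protein Adamtsl2 (-1.64) and the retinol-storing enzyme Lrat (-3.53). Between heart and liver they were those of the phosphatase Ptpn3 (1.81), Gstm1 (2.97), Acacb (3.38), the GTPase regulator Asap2 (1.96), Adamtsl2 (-2.29), Cdkn1a (1.20), Mdm2 (-0.33), Ccng1 (-0.49), Pdk4 (4.14) and Angptl4 (1.18). Between kidney and liver they were those of Asap2 (2.32), Apoa4 (-3.93), Gstm1 (2.79), Azgp1 (3.88), the hyaluronan-binding protein Itih5 (2.72), Cdkn1a (1.45), Mdm2 (-0.31), Ccng1 (-0.92), Casp2 (0.48), Bdh1 (-0.96) and Pdk4 (1.41). The difference between heart and liver of Ccng1 (adjusted p = 0.0354) was lost without replicate number 1 (0.434) or 2 (0.214), and that of Mdm2 (adjusted p = 0.0283) without number 1 (0.331), 2 (0.1) or 3 (0.0922). Both were also lost with the near-identical pairs as 1 library each (0.154 and 0.0904), with RLE scaling and with the 12 libraries of the 2 organs alone. Between kidney and liver, Mdm2 (adjusted p = 0.0379) was lost without number 1 (0.26), 2 (0.11) or 3 (0.136), Bdh1 (adjusted p = 0.0217) without number 1 (0.183) or 2 (0.139), and Casp2 (adjusted p = 0.0253) without number 1 (0.277) or 2 (0.123). Mdm2 and Bdh1 were also lost there with the near-identical pairs as 1 library each (0.0659 and 0.0542), and Mdm2 without chow heart replicate 3 and ketogenic kidney replicate 1 (0.0589) and with the 12 libraries of the 2 organs alone.

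Ketogenic kidney replicate 1 lay nearer the chow kidneys than the other ketogenic kidneys did. Over all 3356 genes that passed without it, outside the fatty acid and ketone lists, 45.95% put it on the ketogenic side of the midpoint, so most put it on the chow side, which was the sign set beforehand for a wrong label, and the 70% set for rejecting one was missed; chow kidneys left out in the same way reached 2.2 to 14.6% and ketogenic replicates 3 and 2 92.6% and 93.7%. Against a mislabelled chow kidney stands the later test of its proliferation, matrix and clock genes, of which 97.1% of 68 put it on the ketogenic side, where left-out chow kidneys reached at most 5%. Another piece of the kidney stays open as an explanation: its proximal tubule markers lay at -0.26 and its distal nephron markers at 0.46 against the mean of the other ketogenic kidneys, and its adipocyte markers at 1.05. A mouse that had eaten, or had fewer ketone bodies, at collection also stays open and was not tested.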

How the results depend on the processing

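The sums of near-identical libraries and the runs without the 2 doubted libraries (chow heart replicate 3 and ketogenic kidney replicate 1) were chosen after the data were seen; the other alternatives were planned. Of 193 alternative values of the results that answer a comparison, 155 stayed within 1.5 times or on their side of the threshold; the cause of the other 38 was not tested, except that fewer libraries or a stricter hypothesis were used where named. Leaving out 1 library gave 1583 to 4689 genes in heart and 412 to 3402 in kidney, and leaving out 1 replicate number gave 37 to 460 genes that differ between heart and kidney, 2335 to 4937 between heart and liver, 1896 to 4009 between kidney and liver and 5 to 175 shared by all 3 organs. Tested against a 1.5-fold change, 352, 187 and 1352 genes passed in heart, kidney and liver. Counting the near-identical pair once gave 1642 genes in heart and 392 differences between heart and kidney; without the doubted libraries these differences were 1333 and the shared genes 488, and at an adjusted p under 0.1 the shared genes were 487. The number of lists passed was 0, 0 and 0 with an estimated correlation in heart, kidney and liver (11, 16 and 9 with camera's preset one) and 19, 6 and 20 with fry. The p53 targets of heart passed only with fry (0.0229); those of kidney gave 0.643 with an estimated correlation, 0.0822 with fry and 0.00122 to 0.0896 without 1 library. Ketone body metabolism in heart turned upward with fry (0.00587), and Car3 in heart went from -4.46, not called, to 1.30 without chow replicate 3 (adjusted p = 0.0142), the highest of -5.02 to 1.30 without 1 library. With the replicate number as a block, 810 genes passed in kidney, 2732 in heart and 6174 in liver, and 709, 4797 and 4289 genes differed between heart and kidney, heart and liver and kidney and liver. The deviations of same-numbered libraries correlated above 0.1 in 2 of 9 pairs within an organ and 5 of 18 across organs. Among these, chow hearts and kidneys did so at each number (0.157, 0.164 and 0.166) and correlated best with their own number, while ketogenic hearts and kidneys gave -0.218 to -0.025. Libraries of different diets, which cannot come from 1 mouse, reached 0.263 (ketogenic kidney 1 with chow kidney 3) and 0.238 (ketogenic liver 1 with chow kidney 1). The values therefore do not show whether a number marks 1 mouse. DESeq2 gave 3257, 1861 and 5590 genes and limma-voom 3068, 1258 and 6070. Scaling by total count lost 10, 7 and 1 of 185, 189 and 180 named genes in heart, kidney and liver and reversed none of the calls.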

Other observations

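The tests of 2 mice that vary as others do and of 1 file deposited 2 times were chosen after the result was seen; the lists of growth, male and female genes were written before they were tested, after the main results, and the change of some of their genes, were known.

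Genes that separate the livers of adult males from those of females and young mice moved with the diet. In liver, 10 of 16 genes typical of adult males rose and 1 fell, with a median log2 fold change of 0.98 (camera adjusted p = 0.000448; adjusted p = 0.216 with an estimated correlation), and 8 of 13 genes typical of adult females or immature mice fell, with a median of -2.74 (adjusted p = 0.000448; adjusted p = 0.216 with an estimated correlation). Cyp2a4 and Hao2 were at -6.72 and -6.45 in liver. Of the 16 genes of the male list, 4 are Mup genes and 2 are Cyp4a genes, which share reads, as Cyp2a4 does with Cyp2a5; these values are uncertain. In kidney, 6 of 13 genes typical of adult male kidneys rose, the uncertain Cyp4a12a among them, with a median of 1.89 (adjusted p = 1.11e-07; adjusted p = 0.132 with an estimated correlation). Cyp2a4 rose there 31.9-fold, the opposite of its direction in liver. Some of these changes, that of Hao2 among them, were known when the lists were written. The p-values of the male and female lists are therefore not independent support. All 18 libraries held at most 7 counts of Xist and at least 990 of the Y-linked gene Ddx3y.

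Single genes of hormone and stress responses changed in liver, while the lists of these responses did not pass by camera. Igfbp1 and Irs2, which insulin and FOXO proteins control, fell by 3.30 and 1.60 on the log2 scale, the mitophagy receptor Bnip3 rose by 2.13, and of 19 insulin and FOXO targets 2 rose and 9 fell (camera adjusted p = 0.0919 and, downward, 0.00275 by fry). Of 22 unfolded protein response genes 3 rose and 10 fell (adjusted p = 0.0955 and 0.269), and of 26 integrated stress response genes 10 fell and 16 did not pass (adjusted p = 0.143 and, downward, 0.0129). In the heart, Fbp2, which acts in glucose handling, rose by 2.13, and Nppb, a wall stress hormone, fell by 1.09. The 12 cardiac stress genes tested there went both ways, with 3 risen and 2 fallen, and their list did not pass (camera adjusted p = 0.848). In the kidney, the calcium binder Calb1 fell by 1.38 and Cyp27a1, a sterol hydroxylase, rose by 1.16.

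Proliferation and matrix genes were lower in all 3 organs, and a loss of every other cell type alike is argued against, since in 3 organs the endothelial or macrophage marker median stayed above -0.2 while the matrix median lay under -0.5. Fewer cells of single types stay open, since fibroblast markers fell as a list in heart and kidney (medians -0.57 and -0.44), macrophage and erythroid markers in heart (-0.72 and -2.08) and cholangiocyte and smooth muscle markers in kidney (-0.59 and -1.07, camera adjusted p = 0.00561 and 0.0195; the latter 0.0678 without ketogenic replicate 3 and 0.0512 without chow replicate 1), all lost with an estimated correlation (adjusted p = 0.474, 0.636, 0.432, 0.474, 0.636 and 0.643). A hypothesis that the data fit is that the chow libraries come from a less mature stage of postnatal growth: genes that decline after birth had medians of -0.82, -0.61 and -0.54 in heart, kidney and liver and a highest camera adjusted p of 0.0131 (adjusted p = 0.061, 0.0492 and 0.216 with an estimated correlation), with 4 of 16, 5 of 19 and 9 of 16 genes fallen and 2 risen in liver. The list was written after the main results were known, so its fall is not independent support for this hypothesis. The heart value is less secure, since the list was not tested without chow replicate 3. Heart genes of the list that did not pass included some that varied widely between the chow hearts, such as Plagl1 (23.81 ± 18.15 CPM), Peg3 (42.64 ± 29.02) and H19 (94.41 ± 86.28). The 4 heart genes that passed, Mest (38.27 ± 7.913), Sox4, Ezh2 and Ndn, varied less. By the treatment protocol both diets began at the same age and lasted as long, which argues against a difference in age. Still, no age at collection is given per library. A difference in pace stays open, and a diet that slows growth cannot be told apart without body weights. The median of male liver genes rose by 0.984, where a delayed maturity would lower it. That list passed by camera at the preset correlation (adjusted p = 0.000448) but not with an estimated one (adjusted p = 0.216). Its Mup and Cyp4a genes share reads, which leaves the split within each family uncertain. The list was also written after the main results were known, so it does not settle the point. Other hours of collection stay open too, since clock genes differ and no hour is given in the labels.

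Ketogenic replicates 1 and 2 of heart and of liver differed by little more than counting noise. They are not 1 file deposited 2 times, because 4 genes with at least 1000 counts (Hbb-b1 and Hbb-b2 in heart, Mup8 and Lars2 in liver) were over 2-fold apart. Against 2 mice that vary as others do stands the observation itself, with no separate test: the higher coefficient of variation of the pairs was 0.478 of the lowest of the other 16. A candidate explanation that stays open is 1 RNA sample made into 2 libraries: for the most variable genes the median absolute log2 ratio of the pair was at most 0.375 of that between replicates 1 and 3, which restates the observation on fewer genes. Littermates with very similar organs were not tested.

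Regrouping the 6 libraries of an organ gives 10 splits, too few for a share under 0.05. The real split gave 3317, 1314 and 6164 genes in heart, kidney and liver, and the highest other gave 0 in each organ by edgeR, where the real split gave 5177, 3859 and 6992 genes at an unadjusted p under 0.05; 1 split in each organ, the real one, reached its count. For lists passed by camera the real split gave 11, 16 and 9 and the highest other 13, 17 and 11, with 6, 2 and 4 of 10 splits as large, so the number of lists says little at the preset correlation. Of these lists 6, 7 and 8 had their lowest adjusted p in the real split. Among the lists named in the text, others of the 10 splits gave as low a p in heart for the tricarboxylic acid cycle (5 splits with the real one), proliferation (3), insulin and FOXO targets (3), fibroblast (2) and erythroid markers (2). In kidney this held for adipocyte (4), smooth muscle (3), fibroblast (2) and cholangiocyte markers (2), peroxisomal genes (3) and p53 targets (2), and in liver for the interferon response (5). The 100 regroupings of all 3 organs decide nothing about the 308 shared genes. Since every other split of an organ gave 0 genes, a regrouping that changes an organ shares 0, and 1 of the 100, the real one, reached the count.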
